A study of Homo sapiens with 6 samples.

How the data were processed

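The series holds 6 RNA sequencing libraries of K1 cells, 3 control and 3 miR-31 KO, grouped by their titles. The series text speaks of duplicates, while the titles number 3 libraries per group, and the titles were followed. Per the labels' protocols RNA was extracted with Trizol and sequencing libraries were made with standard Illumina protocols. Per the submitters' processing notes Bowtie2, HISAT and RSEM and the builds hg19 and hg38 were used, with no role given; versions, the normalization and the test are not given in the sources used here.

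One table was analysed. Its 6 library columns are a signal unit, normalized read counts per gene made by the authors. The values are not whole. Some libraries hold values between 0 and 0.4 where another library of the group has reads, so the original reads were not recovered. Within a tolerance of 0.1, 100%, 98.9% and 65.4% of low values were whole multiples of 1 step in control replicates 2, 3 and 1. In miR-31 KO replicates 1, 2 and 3 the share was 28.6%, 32.8% and 35.4%. The columns of the 2 groups thus differ in this respect. Whether this bears on genes listed at 0 in 1 group was not tested. The log2 fold change column was deposited by the authors as miR-31 KO over control, and its sign matched the group means for every gene. The p-value and adjusted p-value columns were deposited by the authors. The ratio of adjusted p to p for the first gene gives 16806 tested genes by Benjamini-Hochberg adjustment, and the last gene's values place it at rank 3483, so the 986 listed genes are 28.3% of those with an adjusted p under 0.05. Because the genes were already selected, the authors' deposited fold changes and p-values are the main result, as fixed for such a table before the data were examined. The count "adjusted over the list alone" is not given for the gene lists, since it needs the p-values of members that are not listed.

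Gene positions, 3' UTRs and GC content come from GENCODE release 29 on GRCh38, matched by symbol for 966 of the 986 genes; this may not be the annotation the authors used, and the table itself has no coordinates. A total of 23 gene lists were fixed before the data were examined. For lists with 5 or more listed members, higher against lower members were compared with all other listed genes by Fisher's exact test. A hypergeometric test of the number of listed members was added after the data were seen. Both tests treat the genes of a list as independent, so their p-values may be too small where members change together. Seed sites were tested in 953 genes with an annotated 3' UTR, with 100000 permutations within 10 bins of 3' UTR length. The genes named are IFNA1 as the listed gene of the miR-31 locus list, the 10 largest rises and 10 largest falls among genes without overlap between groups and with a mean of at least 10 in the higher group, and up to 4 members of each list by adjusted p; others are marked as chosen after their values were seen. The result of 1 gene that this rule names is not reported here.

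Alternatives were refits with limma 3.58.1 in R 4.3.3 (eBayes with a trend, log2 of the value + 1) on the listed genes, adjusted over 16806 genes. These refits estimate the spread from selected genes and are not genome-wide tests. They covered a pseudocount of 0.1, quantile normalization, a mean of at least 50, the replicate number as a block, and each library left out. A test without a filter and set tests with an estimated correlation need a table of all genes and were not run. The limma step was tested on simulated data with 16806 genes, 3 libraries per group and a dispersion of 0.05, with means drawn from the listed genes' means over all 6 libraries. It recovered 31% of 100 genes changed 2-fold and 80% of 100 genes changed 4-fold, with 4 false calls. Nearly all simulated genes were unchanged and all had 1 dispersion, while the refits used selected genes. These rates therefore do not carry over to the refits. An earlier version of this simulation drew means from the control libraries alone and was replaced because it held genes near 0 that the table does not hold. No 2 libraries matched within sampling noise: the mean chi-square per gene was 7.62 for control replicates 2 and 3 and 7.97 for miR-31 KO replicates 1 and 2, the closest pairs. It was 86.8 and 89.2 for control replicate 1 against control replicates 2 and 3. For miR-31 KO replicate 3 it was 188 and 179 against KO replicates 1 and 2. Each group thus held a close pair and a more distant library. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.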

Results

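Gene expression was measured by RNA sequencing in K1 cells, an established human papillary thyroid carcinoma line. One group of 3 libraries came from control cells and the other group of 3 from cells transfected with a guide RNA against miR-31, a microRNA of chromosome 9p21, here called miR-31 KO. The authors' deposited table holds normalized read counts of 986 genes in the 6 libraries, and the normalized counts of these genes summed to between 545354 and 943360 per library. Total library depth is unknown from this table, so no counting interval is given. Values are means ± SD over the 3 libraries of a group (n = 3) unless stated otherwise. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

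The comparison of miR-31 KO with control cells addressed which transcripts differ between cells in which miR-31 was targeted and control cells. In this design, other differences between the 2 cell populations cannot be told apart from an effect of targeting miR-31. In miR-31 KO 593 genes were higher and 393 were lower, per the authors' deposited table. Among the abundant transcripts, MT1E, a metallothionein that binds zinc and other metals, fell from 3192 ± 275 to 205 ± 19.9 normalized counts, and SLC38A5, an amino acid transporter, fell from 1973 ± 194 to 45.9 ± 31.9. The collagenase gene MMP1 rose from 3416 ± 1722 to 35696 ± 8787, and IQCA1 rose from 14.0 ± 1.69 to 1074 ± 136. MT1E and IQCA1 had the smallest adjusted p-values in the authors' deposited table, 7.39e-174 and 1.39e-124, with log2 fold changes of -3.96 and 6.25; both were singled out after their values were seen. Every listed gene had an adjusted p under 0.05 and an absolute log2 fold change of at least 1, so the table is a selection, and a gene that is not listed cannot be called unchanged. The 3 KO values and the 3 control values did not overlap for 913 of the 986 genes (92.6%, where chance gives 10% for unselected genes). A limma refit of the listed genes called 278 higher and 169 lower, and after quantile normalization it called 177 higher and 282 lower. Quantile normalization gave all libraries the same distribution over these selected genes, which works against an excess in either direction. The reversed balance of calls therefore cannot decide whether the excess of higher genes depends on the authors' scaling. After this step 985 of the 986 genes kept the sign of the deposited fold change.

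Neither MIR31 nor its host gene MIR31HG was among the listed genes, so the targeted locus gave no check of the labels. MIR31 lies on chromosome 9 from 21512115 to 21512185 (GRCh38, minus strand), inside MIR31HG, which spans 21455642 to 21559669. IFNA1, a type I interferon gene on the same chromosome from 21440454 to 21441316, was the 1 listed gene within 1 Mb of MIR31, and its end lies 70799 bp from the start of MIR31. IFNA1 rose from 38.7 ± 11.7 to 171 ± 33.2 normalized counts, with an adjusted p of 2.70e-10 in the authors' deposited table.

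Many of the genes with the largest changes had values near 0 in one group. EPB41L3, a membrane skeleton protein, rose from 3.82 ± 4.91 to 663 ± 229 normalized counts. The serine protease gene TMPRSS15 rose from 3.41 ± 2.11 to 555 ± 75.7, and DIP2C rose from 3.44 ± 2.54 to 475 ± 84.4. CDH11, a cadherin of mesenchymal cells, rose from 0.331 ± 0.568 to 172 ± 37.5. Other genes were listed at 0 in all 3 control libraries and had these normalized counts in miR-31 KO replicates 1, 2 and 3. ANOS1 had 49.7, 67.2 and 76.1, the chemokine gene CCL28 had 43.6, 42.3 and 33.7, and PREX2 had 18.3, 41.1 and 22.4. PRDM9 had 35.0, 13.4 and 18.1, RNF175 had 20.2, 24.2 and 21.7, and XAGE2 had 19.9, 15.3 and 21.01. In the other direction, GAGE2A, one of a family of near-identical cancer-testis genes whose reads may be split between copies, fell from 159 ± 62.5 to 1.07 ± 1.19, HENMT1 fell from 136 ± 6.33 to 3.71 ± 2.99, NHLRC1 fell from 35.7 ± 4.05 to 0.591 ± 0.482, and RNF212 fell from 26.5 ± 13.2 to 0.302 ± 0.508. Listed at 0 in all 3 miR-31 KO libraries were SLITRK2, with 104, 87.2 and 80.6 normalized counts in control replicates 1, 2 and 3, ZNF256 with 35.4, 19.0 and 20.6, OR51B4 with 24.7, 20.04 and 13.7, and NDN with 15.1, 17.03 and 8.81. In total 68 genes were listed at 0 in all control libraries and 11 in all KO libraries. Because genes used by most cell types, such as RBCK1, were among them, a value of 0 is given as listed and no fold is computed against it.

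Inflammatory genes formed the group with the largest share of listed members. Of 35 NF-kappa-B and cytokine genes fixed as a list, 17 were listed, against 2.05 for a random list of that size (hypergeometric adjusted p = 3.87e-11 over 23 lists, if all 35 were among the genes the authors tested). All 17 were higher in miR-31 KO, while 60.1% of all listed genes were (Fisher's exact test, two-sided, adjusted p = 0.000832 over the 4 lists with 5 or more listed members). The neutrophil chemokine gene CXCL3 rose from 775 ± 112 to 2501 ± 255 normalized counts and CXCL2 from 3495 ± 460 to 7584 ± 787. The adhesion molecule gene VCAM1 rose from 36.4 ± 30.5 to 1484 ± 570, and the cytokine gene IL32 rose from 253 ± 29.3 to 937 ± 80.1. In the authors' deposited table their log2 fold changes were 1.69, 1.12, 5.34 and 1.89. VCAM1 had 71.5, 22.1 and 15.6 in control replicates 1, 2 and 3, so its fold depends on control replicate 1. Libraries of a group differed in these genes: control replicate 1 was above both other controls in 13 of the 17, and miR-31 KO replicate 3 was below both other KO libraries in 16. Most of the 17 genes thus shifted together by library, while the hypergeometric and Fisher's exact tests treat them as independent. Both p-values may therefore greatly overstate the support, and a shared shift of these genes between libraries was not separated from an effect of targeting miR-31. For TNFAIP3, SOD2 and IL1B, chosen after their values were seen, control replicate 1 was above KO replicate 3; IL1B had 24935 normalized counts in control replicate 1 and 14155 in KO replicate 3.

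**Figure D1:**
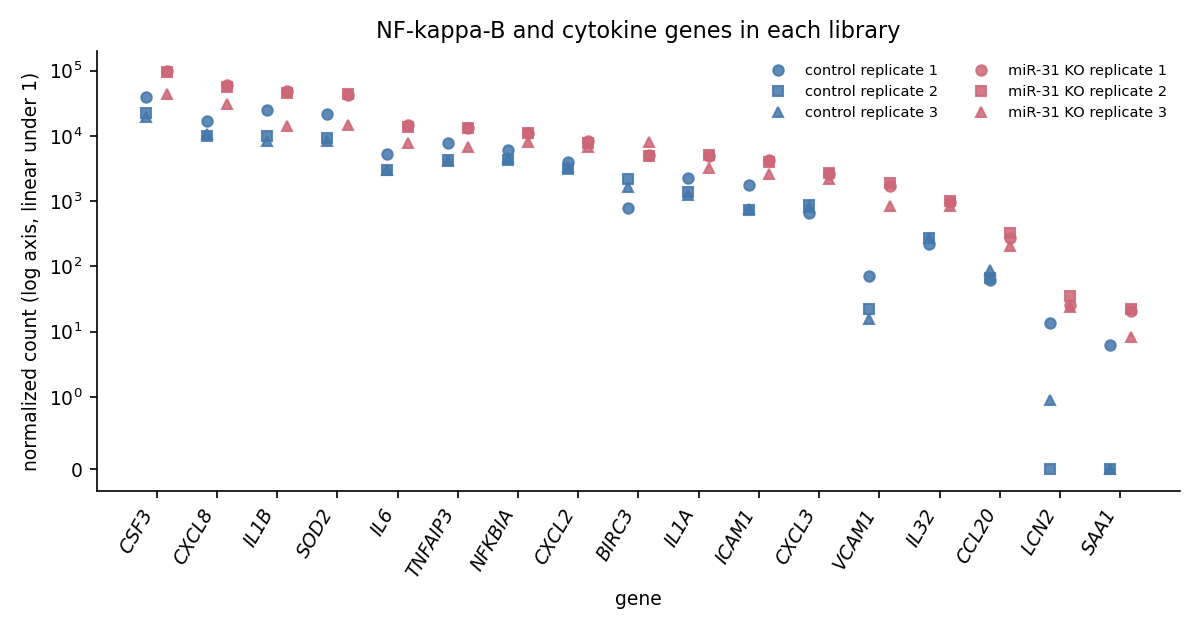
Normalized counts (vertical axis, logarithmic above 1 and linear below) of the 17 listed NF-kappa-B and cytokine genes (horizontal axis) in each library, with controls in blue and miR-31 KO in red and 1 marker shape per replicate number. For 14 of the 17 genes every KO library lies above every control library.

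Epithelial and mesenchymal genes were each listed 7 times. The 7 of 30 epithelial genes compare with 1.76 for a random list of that size (hypergeometric adjusted p = 0.0167 over 23 lists); 5 were lower and 2 higher, and the test of direction against the other listed genes did not pass (Fisher's exact test, adjusted p = 0.163). The keratin gene KRT19 fell from 1405 ± 366 to 469 ± 90.0 and the mucin gene MUC1 from 61.3 ± 2.88 to 11.3 ± 3.604. The junction gene JUP fell from 675 ± 251 to 231 ± 48.2 and the cadherin gene CDH3 from 29.3 ± 5.06 to 3.01 ± 2.73. Of the 2 higher members, ESRP1 rose from 5.48 ± 5.51 to 36.2 ± 9.57 and OCLN from 26.4 ± 8.26 to 79.9 ± 29.9. Both were named after their values were seen. Of 46 mesenchymal and matrix genes, against 2.70 for a random list (hypergeometric adjusted p = 0.130), 6 were higher and 1 lower (Fisher's exact test, adjusted p = 0.254). The gelatinase gene MMP2 rose from 1457 ± 147 to 8017 ± 1963 and the transcription factor gene TWIST2 from 446 ± 47.5 to 1100 ± 15.4, while the collagen gene COL6A3 fell from 64764 ± 11933 to 29900 ± 2296. Of 45 interferon response genes, against 2.64 for a random list (hypergeometric adjusted p = 0.213), 5 were lower and 1 higher (Fisher's exact test, adjusted p = 0.0797). IFI27 fell from 2472 ± 581 to 582 ± 163, IFI6 from 2910 ± 1062 to 982 ± 215 and OAS1 from 723 ± 310 to 272 ± 25.1, and HLA-B, a class I antigen-presenting gene, rose from 1548 ± 93.7 to 3122 ± 599. Control replicate 1 was below both other controls in all 5 lower interferon members and lay a median 0.832 of the way (0.468 for IFI27 to 0.928) from those controls to KO replicates 1 and 2, so the fall rests largely on control replicates 2 and 3. OAS1 had 385, 994 and 789 normalized counts in control replicates 1, 2 and 3.

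**Figure D2:**
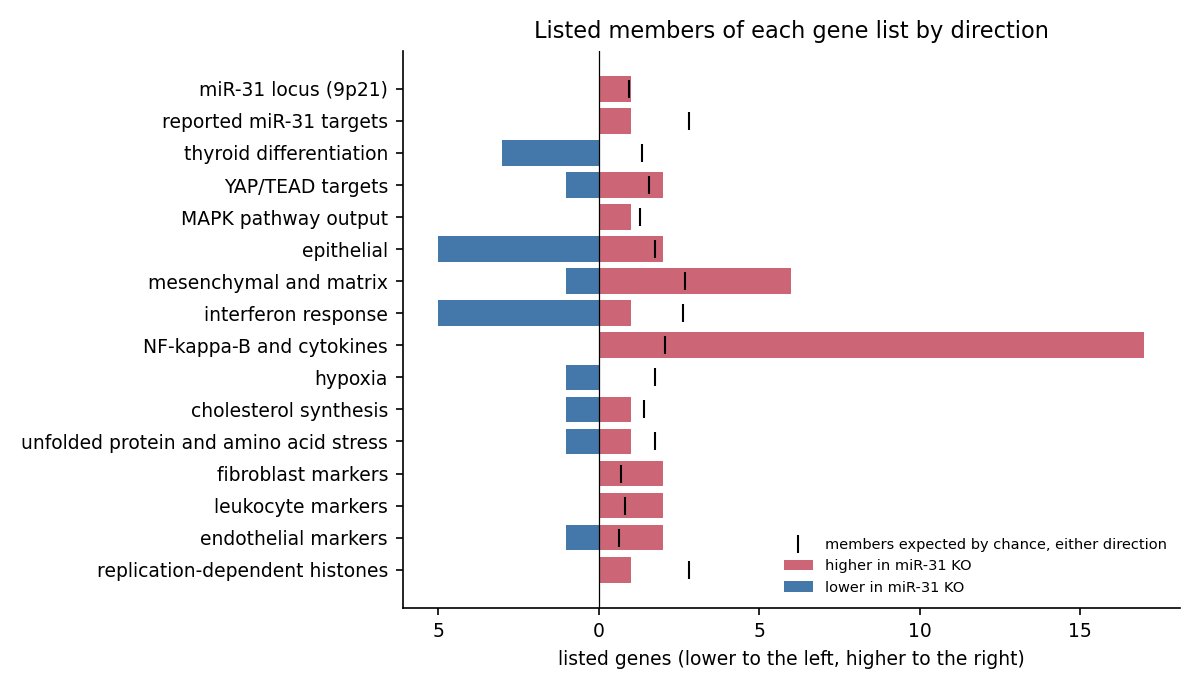
Number of listed genes (horizontal axis) in each gene list with at least 1 listed member, with genes lower in miR-31 KO to the left in blue and genes higher to the right in red. Black ticks give the number expected in either direction for a random list of the same size, 2.05 for the NF-kappa-B list, of which 17 were listed.

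Of 23 thyroid differentiation genes 3 were listed, all lower, too few for a test of direction. DUOXA1, a dual oxidase maturation factor, fell from 47.0 ± 16.2 to 1.28 ± 0.453, the anion exchanger gene SLC26A4 from 71.0 ± 15.5 to 31.1 ± 5.65, and the dual oxidase gene DUOX2 from 23.6 ± 12.8 to 3.81 ± 6.60. Among YAP/TEAD targets the tissue factor gene F3 rose from 682 ± 44.1 to 1556 ± 282 and ANKRD1 from 2.33 ± 2.05 to 14.2 ± 3.53, and IGFBP3 was listed as lower, 827 ± 398 against 271 ± 170, with overlapping groups. EPHA4 was the 1 listed gene of the MAPK output list and rose from 8.09 ± 9.48 to 89.3 ± 19.6. The hypoxia gene CA9 fell from 19.5 ± 5.91 to 2.10 ± 2.87. Of the cholesterol list TM7SF2 rose from 52.6 ± 6.80 to 108 ± 25.4. Of the stress list NUPR1 fell from 65.1 ± 37.0 to 15.9 ± 9.19, and TRIB3, listed at 0 in all controls, had 8.78, 3.14 and 14.3 in the KO replicates. The histone gene HIST1H2AC rose from 88.4 ± 17.3 to 193 ± 11.8. No gene of the proliferation, p53 target, immediate early, Wnt, neural, mitochondrially encoded or broadly used lists was listed.

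Some markers of other cell types were listed, at low values for fibroblast and leukocyte markers. The fibroblast marker LUM, listed at 0 in all controls, had 7.62, 5.87 and 11.5 in the KO replicates, and PDGFRA rose from 4.48 ± 3.51 to 27.2 ± 10.97. The T cell marker CD3D, listed at 0 in all controls, had 3.99, 8.78 and 5.16, and ITGAM was listed with overlapping groups, 12.8 ± 7.21 against 44.3 ± 41.9. Of the endothelial markers TIE1 rose from 996 ± 513 to 4971 ± 974 and KDR from 213 ± 52.0 to 432 ± 54.2, and ERG fell from 474 ± 32.8 to 134 ± 2.25.

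The last comparison asked whether transcripts with sites for miR-31-5p were more frequent among higher than among lower genes. Of 48 reported miR-31 targets fixed as a list, 1 was listed, against 2.82 for a random list of that size. It was the transcription factor gene SOX4, with 2599 ± 1186 normalized counts in control and 5376 ± 1907 in miR-31 KO and overlapping groups. A seed site (8mer, 7mer-m8 or 7mer-A1, in the longest annotated 3' UTR) was present in 114 of 581 higher genes (19.6%) and 70 of 372 lower genes (18.8%). The difference was 0.804 percentage points, with a 95% interval of -4.31 to 5.92 (Fisher's exact test, two-sided, p = 0.801; permutation within 10 bins of 3' UTR length, p = 0.637). Of the 140 sequences of 7 bases with the composition of the seed match, itself included, 105 gave a difference as large. Reported targets with changes below the selection threshold would not be seen in this table.

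Listed genes were not spread evenly over the chromosomes by direction, a comparison chosen after the values were seen. On chromosome 16, 37 of 49 listed genes were lower, and on chromosome 4, 37 of 42 were higher (Fisher's exact test against all other listed genes, adjusted p over 23 chromosomes of 4.94e-06 and 0.00155). On chromosome 8, 23 of 37 were lower (Fisher's exact test, adjusted p = 0.0416). These tests treat genes as independent. When runs of neighbouring listed genes with gaps up to 5 Mb were kept whole and placed at random 10000 times, the share of draws with any chromosome as skewed as 16 was 0.000900, and as skewed as 4 was 0.0665 (0.000600 and 0.0379 with gaps up to 1 Mb). Chromosome 8 was not tested in this way.

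**Figure D3:**
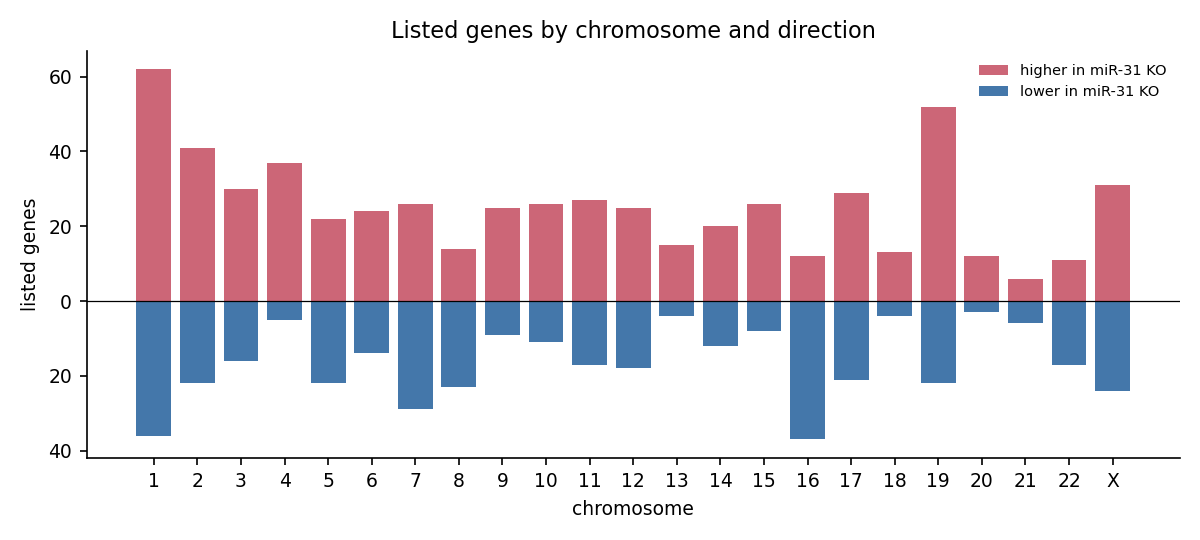
Number of listed genes (vertical axis) on each chromosome (horizontal axis), with genes higher in miR-31 KO above 0 in red and genes lower below 0 in blue. Chromosome 16 has 12 higher and 37 lower genes, and chromosome 4 has 37 higher and 5 lower genes.

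A block of 8 neighbouring genes of chromosome 20p13, between 270863 and 653370 (GRCh38), was listed at 0 in all 3 control libraries. These were C20orf96, ZCCHC3, SOX12, NRSN2, TRIB3, RBCK1, TBC1D20 and SRXN1, singled out after their values were seen. The annotation places 10 protein coding genes there; the other two, CSNK2A1 and TCF15, were not listed and were not analysed here. In the KO libraries their normalized counts lay between 0.240 and 20.8. RBCK1, part of a ubiquitin ligase complex, had 20.8, 12.7 and 13.8 in KO replicates 1, 2 and 3, and TBC1D20 had 12.7, 13.7 and 16.7.

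**Figure D4:**
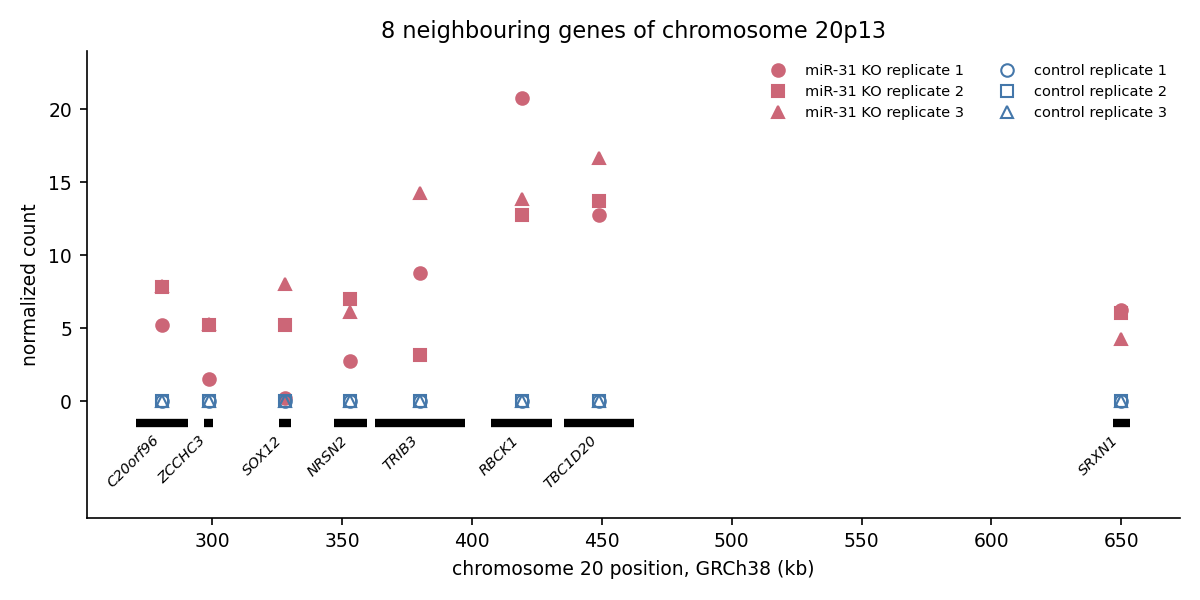
Normalized counts (vertical axis) of the 8 listed genes of chromosome 20p13 at their positions (horizontal axis, kb, GRCh38; black bars are genes), with miR-31 KO libraries in red and controls as open blue markers. All control values are 0, and the highest KO value is 20.8.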

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

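The limma refit with no other change, the fold threshold of 2 and the set of 4 libraries were chosen after the data were seen. The authors' deposited table gave 986 genes and 760 at an adjusted p under 0.01. An absolute log2 fold change of 2 or more left 452. The limma refit called 447, 389 with a pseudocount of 0.1, 459 with quantile normalization and 261 with a mean of at least 50, where fewer genes were tested. Quantile normalization shifted the median log2 fold change by -0.44. Leaving out 1 library gave between 156 and 420 calls: 182 without control replicate 2, 189 without control replicate 3, 156 without miR-31 KO replicate 1 and 185 without replicate 2. It gave 420 without control replicate 1 and 396 without KO replicate 3, each the most distant library of its group. Control replicates 2 and 3 against KO replicates 1 and 2 gave 505. Whether the spread from these libraries accounts for all of the differences was not tested. With the replicate block the refit called 417. Same-numbered libraries did not deviate together (correlations across genes of 0.20, -0.13 and 0.15), so the numbers were not taken to pair the samples. The seed site difference was -3.21 points at an absolute log2 fold change of 2 or more (Fisher's exact test, p = 0.511, and the cause was not tested). It stayed positive with the other settings. In refits of all 986 genes it depends on signs alone, which changed for at most 1 gene, so these refits add no support. Of 715 values of named genes across settings, 487 kept their call, 228 lost it and 0 reversed; these genes were selected for their change. The 210 genes with a mean under 10 had low values, and whether depth limits them was not tested.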

Other observations

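The tests of mixing, of chromosome placement, of the block of chromosome 20p13 and of the interferon genes, and the gene families, were chosen after the results were seen. Among 11 gene families picked by symbol, the protocadherins, adhesion molecules of the cadherin superfamily, were all lower in miR-31 KO, 7 of 7 listed. All but PCDH20 are neighbours on chromosome 5, between 140827958 and 141512979 (GRCh38), and neighbouring listed genes tend to share direction, so they do not count as independent genes, and the test of this family (Fisher's exact test against the other listed genes, adjusted p = 0.0170 over 11 families) is not taken as support. PCDHA6 fell from 47.1 ± 11.6 to 4.43 ± 3.47 normalized counts and PCDHB14 from 31.9 ± 7.96 to 4.79 ± 4.64 (SD, n = 3). Clustered protocadherins are similar in sequence, and a split of reads between them was not tested. None of the other 10 families passed (Fisher's exact test, smallest adjusted p = 0.285). Of these, 4 had all listed members higher: secretory phosphoproteins of chromosome 4q (6 genes), CXC and CC chemokines (5), AKR1C genes (3) and HOXC genes (3). The listed IGF-binding proteins (3) and metallothioneins (2) were all lower. As with the protocadherins, neighbouring members such as CXCL2 and CXCL3 on chromosome 4 do not count as independent genes. Both directions occurred in the solute carriers (16 of 20 higher), ZNF zinc finger genes (26 of 41), matrix metalloproteinases (3 of 5) and GAGE, XAGE and MAGE genes (5 of 9).

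Control replicate 1 and miR-31 KO replicate 3 lay between the other libraries of the groups, in inflammatory genes among others. Position was scaled from 0 at a library's own group to 1 at the other group. In control replicate 1 the NF-kappa-B members had a median position of 0.236 (bootstrap 95% interval 0.0294 to 0.295), and 11 genes near 0 in the other controls and high in KO replicates 1 and 2 had -0.00200 (-0.00379 to 0.0107), where a mixture with KO RNA would move both alike. The interval of the NF-kappa-B members reaches below the bound of 0.1 set for the test. In addition, 10 genes low in KO replicates 1 and 2 and high in the other controls had 0.210 (0.0974 to 0.406). By the rule set for the test a mixture stays open. The intervals of the 11 genes and of the NF-kappa-B members do not overlap, however. For these genes, this argues against a mixture as the whole source of the NF-kappa-B position in control replicate 1. The 6 listed interferon members had a median of 0.792 in control replicate 1. In KO replicate 3 the NF-kappa-B members had 0.470 (0.258 to 0.611), and the same 10 genes had 0.0204 (-0.0133 to 0.0679), whose upper bound passes the 0.05 set for the test. The 11 genes had 0.0799 (-0.0271 to 0.446) there, so a mixture with control RNA stays open too. The intervals of the 10 genes and of the NF-kappa-B members in KO replicate 3 do not overlap. This argues against a mixture as the whole source of the NF-kappa-B position there, although the interval of the 11 genes overlaps both. A scaling error of control replicate 1 is argued against, since its median log2 shift was 0.253 for higher and -0.176 for lower genes. A difference in inflammatory state between cultures, before or during harvest, remains a hypothesis with no test here.

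The 8 genes of chromosome 20p13 listed at 0 in the controls lay within 1 Mb. Of 10000 random placements of the 68 genes at 0, 0 put as many in such a window (highest number, 5). These placements treat genes as independent, while neighbouring listed genes tend to share direction, so they may overstate how unusual the block is. Low depth is argued against as far as counting error goes: the low values of control replicates 2 and 3 are almost all whole multiples of 1 and 0.98, so 1 read is close to 1 normalized count there, and the KO level of the 8 genes would give 131.6 reads in these 2 libraries, where 0 are listed. The genes were picked for their 0, but a Poisson probability multiplied by the number of sets of 8 among 16806 genes stays far under the 0.05 set for the test. This takes reads as independent and leaves out the spread between libraries, and total depth is unknown. A candidate explanation is that the region is missing in the control cells and that some KO cells or other cells in the KO libraries carry it. KO replicate 3 held 39.08% of the summed value, inside the 95% range of random sets of other genes at 0 in the controls (22.0% to 44.7%) and outside their quartiles (29.3% to 36.7%), so a small share of other cells could be neither shown nor excluded; expression in all KO cells would give similar ratios. CSNK2A1, which lies between TBC1D20 and SRXN1, was not listed, so a single missing segment across the block was not tested, and neither were a failed estimate in the control libraries or control and KO cells from different lineages of K1.

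Chance placement is argued against for chromosome 16 and stays open for chromosome 4: with runs of neighbouring genes kept whole, the larger share of random placements with any chromosome as skewed was 0.0008999 for chromosome 16, and 0.06649 for chromosome 4, where runs with gaps up to 1 Mb gave 0.0379. GC content of the transcripts does not explain either skew, since at least 97.03% of the log odds remained with GC in the model. Lower genes of chromosome 16 had a median log2 fold change of -1.642 (bootstrap 95% interval -1.91 to -1.47) against -1.576 for lower genes elsewhere. Because the table holds only genes with an absolute log2 fold change of at least 1, both medians lie below -1 by selection, so loss of 1 copy of chromosome 16 in the KO cells cannot be told apart from other causes, although the median lies past the bound that had been set before the result was seen. Neighbouring listed genes within 1 Mb shared a direction in 65.78% of 415 pairs, against 52.2% after permuting directions (p = 0.0001, the smallest that 10000 permutations can give). Differences in DNA copies between the cell populations could give such neighbourhoods, and no DNA data were used here.

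Loss of repression through miR-31-5p seed sites is argued against as the source of the excess of higher genes, since the difference in share of genes with a site was 0.8041 percentage points and its 95% upper bound of 5.92 lies under the 10 points set before the test; smaller effects on genes that are not listed stay untested. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real one, the real one itself, with 447 genes against at most 1 in the others. With 10 splits a share under 0.05 cannot be reached, and the genes had been selected for the real split. An interferon response to transfected nucleic acid would raise interferon genes with the inflammatory genes. Of the listed interferon members 16.67% (1 of 6) were higher, with an exact 95% interval of 0.421% to 64.1%. This interval treats related genes as independent and cannot decide the question. The other 5 were lower, and the median log2 fold change of the 6 was -1.44. The fall of these 5 genes rests largely on control replicates 2 and 3, and HLA-B and the type I interferon gene IFNA1 rose. Such a response is therefore neither shown nor argued against. Members that are not listed stay untested.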
